A study of Homo sapiens
Mus musculus with 12 samples.

How the data were processed

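Messenger RNA was measured in 12 samples of glioblastoma xenografts grown in mouse brain, and the labels list both human and mouse as the organisms. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, its quality was examined on a Bioanalyzer, and biotin-labelled cRNA made from 5 µg was hybridised to 1-colour human Affymetrix arrays. The deposited values are intensity values on a linear scale, 1 per probe set and array, which the authors made with MAS5 per the submitters' processing notes. The version of MAS5, its detection calls and any further filter are not given in the sources used here. The deposited signals of all 12 arrays were above 0 and had the same trimmed mean of 150 (2% trimmed at each end), so each array had been scaled to a common level, and no further scaling was applied. Such scaling removes any difference in the trimmed mean between arrays, whereas other measures of the signal, such as the median, can still differ. RNA of mouse cells can bind human probe sets in part, so that signal from the host brain and from the tumour is not separated by these arrays.

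The table held 54675 probe sets. Control probe sets, 62 in number, were left out of all tests and used only for the ratios of 3' to 5' signal. In the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none, and probe sets with several symbols or none were left out. The symbols of 54 probe sets with 1 symbol had a gene identifier that the RefSeq gene table did not list and were kept as given, and 0 of the matched symbols differed from that table. VTN, the αv ligand vitronectin, had only probe sets that it shares with SEBOX and was therefore not measured as a gene. For each of the 19775 genes with a probe set, the probe set with the highest mean over the 12 arrays was used. Genes were tested if that mean reached the median of all non-control probe sets, a signal of 31.9, which left 11805 genes and removed 7970. Signals were transformed as log2(signal + 16), so a fold change is on this scale and understates the change of genes with low signal.

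Groups came from the sample labels: 4 control arrays, 4 arrays after 1 h and 4 after 8 h of cilengitide. The groups, the 3 comparisons, the gene lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the package data.table for reading, by a linear model over all 12 arrays with a mean per group and moderated variances with an intensity trend. P-values were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 counted as changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Array measures (median and upper quartile of signal, 3' to 5' ratios, the first principal component and marker lists) were compared with exact two-sided permutation tests, whose smallest p for 4 against 4 arrays is 0.0286, while the trimmed mean, equal on all arrays, was not tested. For arrays the number of replicates limits the precision.

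The text names up to 10 genes per direction and comparison that pass the test with separate groups, the 3 genes with the smallest p, up to 4 members per list with the smallest p, and the integrin subunits ITGAV, ITGB3, ITGB5 and ITGB1 together with FN1 and VTN. Members that passed when adjusted over their list alone were named as well, a choice made after their values were seen. Genes of the Y chromosome and XIST were not named.

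In total 33 gene lists were fixed. The 26 pathway lists were RGD-binding integrin subunits, other integrin subunits, RGD-containing ligands and matrix, focal adhesion, YAP/TEAD targets, SRF and actin targets, immediate early genes, MAPK feedback, NF-κB inflammatory genes, TGF-β targets, hypoxia, mitosis, DNA replication, p53 targets, apoptosis regulators, the unfolded protein and integrated stress response, heat shock, cholesterol synthesis, interferon response, angiogenic factors, matrix proteases and inhibitors, mesenchymal glioblastoma genes, proneural and stem genes, ribosomal proteins, oxidative phosphorylation and glycolysis. The 7 marker lists were neuron, oligodendrocyte, astrocyte, microglia and macrophage, endothelium, pericyte and red blood cell. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 90 tests, 30 lists in 3 comparisons. The microglia and macrophage, endothelium and red blood cell lists had fewer than 5 tested members and were described without a camera test. No call by camera held with an estimated correlation. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move one way on balance without comparing them with other genes.

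The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a filter at the 75th percentile, probe sets that can match several transcripts left out, all probe sets, no intensity trend, robust variance shrinkage, only the 2 groups compared, the replicate number as a block, array weights, a minimum log2 fold change of 1, an estimated correlation, fry, each array left out in turn, and the controls split between the effects. Control replicates 1 and 2 left out, and each of the 6 pairs of controls left out in turn, were added after the data had been seen. The fits were tested on simulated data made from the tested genes' means and spreads, with 200 of 11805 genes changed in each of 10 simulations. The test recovered 50.0%, 52.5% and 50.2% of genes changed by a factor of 1.5 at 1 h against control, 8 h against control and 8 h against 1 h, 83.5%, 84.4% and 83.3% of those changed by a factor of 2, and 96.5%, 96.3% and 96.2% of those changed by a factor of 3. False calls made up 4.05% to 5.72% of all calls. A shift of 0.2 in the hypoxia list at 1 h was called in 10 of 10 simulations. Noise was drawn independently for each gene, so correlated differences between arrays were not simulated. Fewer than 200 changed genes, for which the Benjamini-Hochberg adjustment is stricter, were not simulated either.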

Results

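Expression was profiled in glioblastoma xenografts, human brain tumours growing in the brains of mice, after exposure to cilengitide. Cilengitide is a cyclic peptide that carries the RGD motif of matrix proteins and blocks the αv integrins that bind vitronectin and other matrix ligands. Labelled RNA from 12 samples was hybridised to human Affymetrix arrays, and the 12 arrays fell into 3 groups of 4. The control group came from a tumour without exposure, the second group from a tumour exposed for 1 h and the third from a tumour exposed for 8 h. Each group came from a tumour with its own number, so tumour and exposure could not be told apart in any comparison. The descriptions call the 4 arrays of a tumour biological replicates, and the design text speaks of replicate mouse brains, but no label ties an array to an animal. The p-values therefore measure the spread between these arrays. The number of arrays, 4 per group, limits the precision, and the median standard error of a log2 difference was 0.134 over the 11805 genes tested.

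All arrays had been scaled alike, to a trimmed mean signal of 150, and correlated with each other at r = 0.961 to 0.983 across genes, which are not independent replicates. Control replicates 1 and 2 stood apart from the other 10 arrays. Their scores on the first principal component, which carried 24.9% of the variance, were -33.6 and -28.7, against 2.89 to 10.4 on the other 10. Their median signals were 44.5 and 43.1, against 33.7 to 36.3. Of the 5 tested markers of myeloid and red blood cells, 3 also followed this division. AIF1, a calcium-binding protein of microglia, had log2 signals of 9.51 and 8.98 in control replicates 1 and 2 and at most 8.18 on the other 10 arrays. FCER1G, an Fc receptor subunit of myeloid cells, had 6.97 and 6.94 against at most 6.50, and HBB, the β chain of haemoglobin, had 7.72 and 8.27 against at most 7.23. The myeloid markers LAPTM5, with 6.83 and 5.82 against at most 6.45, and CSF1R, with 6.02 and 5.87 against at most 6.38, did not. The share of all genes that followed this division was not determined. The microglia and macrophage list differed from the control by a log2 difference of -0.41 at 1 h and -0.48 at 8 h. The exact two-sided permutation p was 0.0286 for each, the smallest that 4 against 4 arrays allow, and the adjusted p over 36 such tests was 0.343. The ratios of 3' to 5' signal were 0.991 to 1.06 for GAPDH and 1.11 to 1.23 for ACTB, from control probe sets near the top of the signal range.

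**Figure D1:**
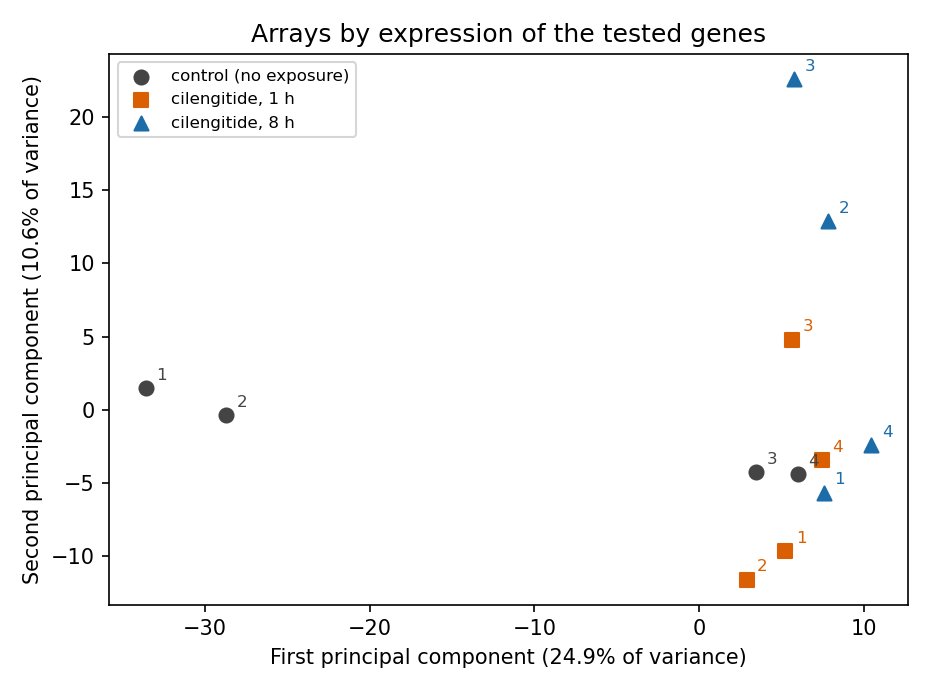
Scores of the 12 arrays on the first principal component (horizontal axis, 24.9% of the variance) and the second (vertical axis, 10.6%) of the log2 signals of the tested genes; each point is an array, numbered by replicate, with circles for control, squares for 1 h and triangles for 8 h of cilengitide. Control replicates 1 and 2 lie at -33.6 and -28.7 on the horizontal axis, and the other 10 arrays lie between 2.89 and 10.4.

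The first question was whether the transcripts of the drug's targets differed with exposure. ITGAV, the αv subunit that the target integrins share, differed from the control by a log2 difference of -0.01 at 1 h (SE 0.09, 95% confidence interval -0.19 to 0.17) and -0.01 at 8 h (interval -0.19 to 0.17). ITGB5, a β partner of αv, differed by -0.11 at 1 h (interval -0.28 to 0.06) and -0.00 at 8 h (interval -0.17 to 0.16). ITGB3, another β partner of αv, had differences of 0.19 and 0.30 (SE 0.18), with intervals of -0.18 to 0.56 and -0.07 to 0.67, and only 2 of its 5 probe sets shared that sign. Without probe sets that can match several transcripts its differences were -0.26 and -0.40, and without control replicates 1 and 2 they were -0.04 and 0.07. ITGB1, the β subunit of the fibronectin receptor, differed by -0.08 at 1 h and -0.00 at 8 h (SE 0.05). None of these genes passed limma's test, with adjusted p from 0.429 for ITGB3 at 8 h to 0.992 for ITGB5 at 8 h. The list of 6 measured RGD-binding integrin subunits had mean differences of -0.07 at 1 h and -0.05 at 8 h, with camera adjusted p of 0.407 and 0.760. Of its members, 0 passed when adjusted over the list alone and 0 over all genes, by limma, and 1 was below an unadjusted p of 0.05 at each time: ITGA5 at 1 h (-0.44, SE 0.17) and ITGB8 at 8 h (-0.34, SE 0.14). ITGA5 had -0.12 at 1 h without control replicates 1 and 2, and ITGB8 had -0.14 at 8 h without 8 h replicate 3.

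After 1 h of exposure, transcripts of the extracellular matrix were lower than in the control tumour. The list of RGD-containing ligands and other matrix proteins fell by 0.27 on the log2 scale on average, and 19 of its 23 measured members had lower means (1 h SD 0.08 and control SD 0.14 of the list mean, n = 4 arrays each). COL6A3, a chain of type VI collagen, had a log2 difference of -1.01 (SE 0.26) and FBN1, the microfibril protein fibrillin, -0.57 (SE 0.13). FN1, which encodes fibronectin, had -0.45 (SE 0.14), with all 5 of its probe sets lower, and EDIL3, an RGD-containing αv ligand, had -0.26 (SE 0.07). These 4 genes together with COL1A1, COL1A2 and COL4A1 made 7 members that passed adjusted over the list alone, with adjusted p from 0.0078 to 0.0343, while 0 passed over all genes and 13 were lower at an unadjusted p under 0.05 by limma. The list's camera adjusted p was 1.6e-05, and adjusted p = 0.785 with an estimated correlation. Without control replicates 1 and 2 the mean difference was -0.15 with a camera adjusted p of 0.00497 (adjusted p = 0.954 with an estimated correlation). COL6A3 then had -0.35, FBN1 -0.29, FN1 -0.28, COL1A1 -0.24, COL1A2 -0.24, COL4A1 -0.15 and EDIL3 -0.20. The list means of these 2 control arrays were 0.27 and 0.26 relative to the mean of all arrays, those of the other controls 0.03 and 0.02, and those at 1 h -0.17 to 0.01. On the same scale all 4 arrays at 1 h were also lower than control replicates 3 and 4 for the microglia and macrophage list (-0.20 to -0.02 against 0.13 and 0.02) and for HBB (-0.39 to -0.11 against -0.08 and -0.09). Of the microglia and macrophage markers, AIF1 and LAPTM5 were lower in this way, while FCER1G and CSF1R were not. Matrix proteases and their inhibitors were lower as well, with a mean of -0.19, 15 of 17 members lower and a camera adjusted p of 0.0197 (adjusted p = 0.785 with an estimated correlation). MMP14, a membrane-bound matrix metalloprotease, had a difference of -0.84 (SE 0.28) and PLAU, the urokinase plasminogen activator, -0.23 (SE 0.09), and 0 members passed adjusted over the list alone or over all genes by limma, with 3 lower at an unadjusted p under 0.05. The protease mean was -0.09 without control replicates 1 and 2 (camera adjusted p = 0.572), where MMP14 had -0.34 and PLAU -0.12. The protease call also ended without control replicate 1 (-0.14), control replicate 2 (-0.18) or 1 h replicate 2 (-0.18), and with no filter (-0.13), a filter at the 75th percentile (-0.14) or without probe sets that can match several transcripts (-0.12).

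Cholesterol synthesis and hypoxia genes were also lower at 1 h. All 10 measured genes of cholesterol synthesis and uptake had lower means, and the list fell by 0.40 on average (camera adjusted p = 1.03e-05, and adjusted p = 0.785 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, had a log2 difference of -0.72 (SE 0.23), IDI1, the isopentenyl-diphosphate isomerase, -0.55 (SE 0.15) and SQLE, the squalene epoxidase, -0.38 (SE 0.10). With INSIG1, LSS and STARD4 these made 6 members that passed adjusted over the list alone, against 0 over all genes and 6 at an unadjusted p under 0.05 by limma. Without probe sets that can match several transcripts, IDI1 had 0.13 at 1 h, as COL1A2 of the matrix list had 0.01. Of 23 hypoxia genes, 22 had lower means, with an average of -0.18 (camera adjusted p = 2.12e-05, and adjusted p = 0.785 with an estimated correlation). VEGFA, the vascular endothelial growth factor, had -0.25 (SE 0.10), DDIT4, an inhibitor of mTOR signalling, -0.21 (SE 0.08) and P4HA1, a collagen prolyl hydroxylase, -0.19 (SE 0.08), and 0 members passed adjusted over the list alone or over all genes by limma, with 8 lower at an unadjusted p under 0.05. Control replicates 1 and 2 had list means of 0.58 and 0.45 for cholesterol synthesis and 0.32 and 0.29 for hypoxia, and the other controls lay at -0.05 and -0.02, and at -0.05 and -0.00. Without these 2 arrays the means at 1 h were -0.13 (camera adjusted p = 0.330) and -0.02 (camera adjusted p = 0.698). HMGCS1 then had -0.23, IDI1 -0.34, SQLE -0.27, INSIG1 -0.12, LSS -0.06 and STARD4 -0.32, and VEGFA had -0.03, DDIT4 -0.08 and P4HA1 -0.10.

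Higher at 1 h were genes of the interferon response, DNA replication, heat shock and oxidative phosphorylation. All 18 measured interferon-response genes had higher means, by 0.25 on average (camera adjusted p = 0.000118, and adjusted p = 0.785 with an estimated correlation). ISG15, a ubiquitin-like protein induced by interferon, had a difference of 0.44 (SE 0.17) and MX1, an antiviral GTPase, 0.41 (SE 0.16). The DNA replication list had a mean of 0.15 with 18 of 21 members higher, among them the helicase subunits MCM2 (0.40, SE 0.12) and MCM6 (0.26, SE 0.09), and a camera adjusted p of 0.000899 (adjusted p = 0.785 with an estimated correlation). All 9 heat shock genes had higher means, by 0.17 on average (camera adjusted p = 0.00607, and adjusted p = 0.785 with an estimated correlation), including the small chaperone HSPB1 (0.24, SE 0.08). Oxidative phosphorylation genes had a mean of 0.09 with 19 of 22 higher (camera adjusted p = 0.0197, and adjusted p = 0.785 with an estimated correlation). In these 4 lists 0 members passed adjusted over the list alone or over all genes by limma, and 7, 6, 2 and 1 members were higher at an unadjusted p under 0.05. Without control replicates 1 and 2 the 4 means were 0.07, 0.00, 0.03 and -0.02, and none of the 4 lists was called. ISG15 then had 0.10, MX1 0.23, MCM2 0.13, MCM6 0.10 and HSPB1 0.11. The heat shock call also ended without control replicate 1 (0.11), and the oxidative phosphorylation call ended without control replicate 1 (0.05), control replicate 2 (0.05) or 1 h replicate 1 (0.06), with quantile normalization (0.07), a filter at the 75th percentile (0.09) or without probe sets that can match several transcripts (0.03).

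**Figure D2:**
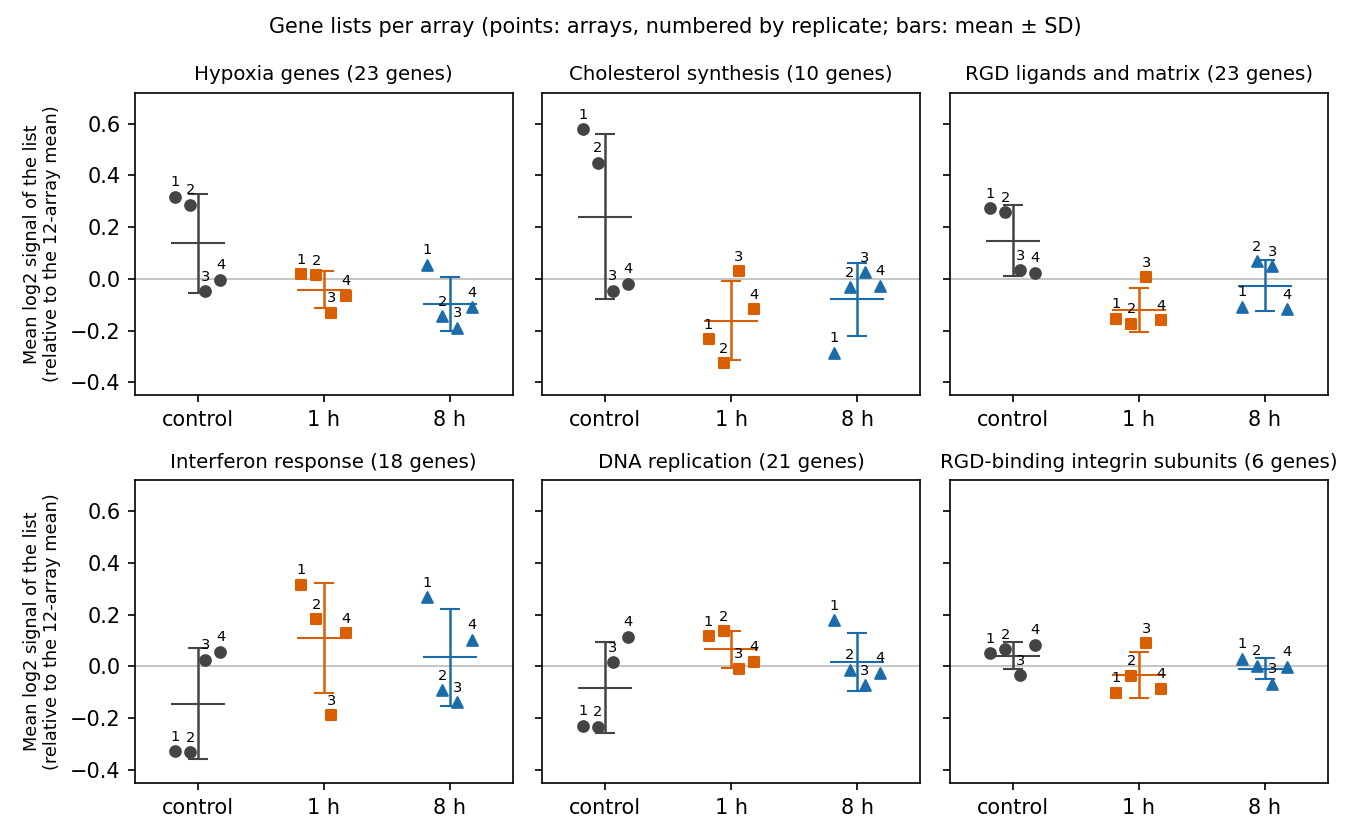
Mean log2 signal of 6 gene lists on each array, relative to the mean of the 12 arrays (vertical axis, log2 units), by group (horizontal axis); points are arrays numbered by replicate, and the bars show the mean ± SD of 4 arrays. Control replicates 1 and 2 lie at 0.58 and 0.45 for cholesterol synthesis and at -0.33 and -0.33 for the interferon response, while control replicates 3 and 4 lie at -0.05 and -0.02 and at 0.03 and 0.06.

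Over all genes at 1 h, limma called 0 of 11805 genes at an adjusted p under 0.05. At an unadjusted p under 0.05, 554 genes were higher and 570 lower. Their sum of 1124 compares with 590 for both signs together if arrays differed by chance independently for each gene. Other groupings of the same 8 arrays gave 241 to 1615, and the sum became 549 without control replicates 1 and 2. At 1 h 4.00% of genes had groups that did not overlap, against 2.86% by chance. The smallest p belonged to OLFM1, an olfactomedin of neural tissue, with a log2 difference of -1.83 (SE 0.29, adjusted p = 0.0892) from a low control mean of 6.47 on the log2 scale. FUT6, a fucosyltransferase, had -0.89 (SE 0.18) and TJAP1, a tight junction protein, -0.61 (SE 0.13), each with an adjusted p of 0.402. OLFM1 passed, with an adjusted p of 0.0475, when probe sets that can match several transcripts were left out before choosing a probe set per gene, which reduced the number of genes tested, and it was the gene called when 8 h replicate 4 was left out (adjusted p = 0.0470).

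After 8 h of exposure, hypoxia genes were lower than in the control tumour. Of 23 measured hypoxia genes 22 had lower means, and the list fell by 0.23 on average (8 h SD 0.11 and control SD 0.19 of the list mean, n = 4 arrays each). EGLN3, an oxygen-sensing prolyl hydroxylase, had a log2 difference of -0.69 (SE 0.18), PFKFB4 and PFKFB3, which set the level of a glycolytic activator, had -0.55 (SE 0.16) and -0.33 (SE 0.09), and ANKRD37, an ankyrin-repeat protein, had -0.50 (SE 0.12). These 4 members passed adjusted over the list alone, against 0 over all genes and 11 at an unadjusted p under 0.05 by limma. The list's camera adjusted p was 9.56e-06, and adjusted p = 0.785 with an estimated correlation. Without control replicates 1 and 2 the mean was -0.07 (camera adjusted p = 0.334), and EGLN3 had -0.36, PFKFB4 -0.27, PFKFB3 -0.24 and ANKRD37 -0.34.

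Cholesterol synthesis and matrix genes were lower at 8 h too. All 10 cholesterol genes again had lower means, with an average of -0.32 (camera adjusted p = 0.000957, and adjusted p = 0.785 with an estimated correlation). HMGCS1 had -0.63 (SE 0.23), INSIG1, which holds back the sterol-sensing machinery, -0.49 (SE 0.18) and SQLE -0.29 (SE 0.10), and 0 members passed adjusted over the list alone or over all genes by limma, with 6 lower at an unadjusted p under 0.05. The matrix list had a mean of -0.17 with 15 of 23 members lower (camera adjusted p = 0.0447, and adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone, 4 members were lower and 1 higher, against 0 over all genes, with 7 lower and 1 higher at an unadjusted p under 0.05 by limma. THBS1, the matrix glycoprotein thrombospondin, had -0.42 (SE 0.10), COL6A3 -0.97 (SE 0.26), FBN1 -0.47 (SE 0.13) and EDIL3 -0.21 (SE 0.07), while TNC, the matrix glycoprotein tenascin, had 0.25 (SE 0.07). The means of the cholesterol and matrix lists were -0.05 and -0.06 without control replicates 1 and 2, with camera adjusted p of 0.721 and 0.567. HMGCS1 then had -0.14, INSIG1 -0.04 and SQLE -0.18, and THBS1 had -0.32, COL6A3 -0.31, FBN1 -0.19, EDIL3 -0.15 and TNC 0.11. The matrix call also ended without control replicate 1 (-0.13), control replicate 2 (-0.14), 1 h replicate 2 (-0.17), 8 h replicate 1 (-0.15) or 8 h replicate 4 (-0.14), with no filter (-0.17) and without probe sets that can match several transcripts (-0.12).

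Interferon-response and oxidative phosphorylation genes were higher at 8 h. The interferon list had a mean of 0.18 with 17 of 18 members higher (camera adjusted p = 0.0432, and adjusted p = 0.799 with an estimated correlation), among them IFI44 (0.40, SE 0.16) and MX1 (0.38, SE 0.16), and 0 passed adjusted over the list alone or over all genes by limma, with 2 higher at an unadjusted p under 0.05. Oxidative phosphorylation genes had a mean of 0.11 with 21 of 22 higher (camera adjusted p = 0.00888, and adjusted p = 0.785 with an estimated correlation). COX4I1, a subunit of cytochrome c oxidase, had 0.31 (SE 0.07) and was the 1 member that passed adjusted over the list alone, against 0 over all genes and 6 higher at an unadjusted p under 0.05 by limma. NDUFV2, a subunit of complex I, had 0.20 (SE 0.08). Without control replicates 1 and 2 the means of both lists turned to -0.01 and -0.00, where IFI44 had -0.01, MX1 0.20, COX4I1 0.17 and NDUFV2 0.13, and with quantile normalization neither list was called (camera adjusted p = 0.0768 for each). The interferon call also ended without control replicate 1 (0.12), control replicate 2 (0.12), 1 h replicate 2 (0.18), 8 h replicate 1 (0.10) or 8 h replicate 4 (0.16), and the oxidative phosphorylation call without control replicate 1 (0.07) or control replicate 2 (0.07). Both calls ended with a filter at the 75th percentile (0.18 and 0.11) and without probe sets that can match several transcripts (0.15 and 0.07).

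Over all genes at 8 h, limma called 0 of 11805 genes, with 923 higher and 821 lower at an unadjusted p under 0.05, while other groupings of the same 8 arrays gave 265 to 1642. The sum of 1744, against 590 by chance on the same assumption as at 1 h, became 877 without control replicates 1 and 2. At 8 h 6.45% of genes had groups that did not overlap against 2.86% by chance. An adjusted p under 0.1 was reached by 7 genes. FUBP3, a single-stranded nucleic acid binding protein, had a log2 difference of -0.84 (SE 0.15), with 1 of its 2 probe sets lower, MFAP2, a microfibril-associated glycoprotein, had -0.78 (SE 0.14), and SNRPF, a core protein of the spliceosome, had 0.44 (SE 0.08), each with an adjusted p of 0.0961. Control replicates 3 and 4 had log2 signals of 9.68 and 9.42 for FUBP3, 7.92 and 7.66 for MFAP2 and 10.40 and 10.56 for SNRPF. The 8 h arrays had 8.57 to 9.11, 6.93 to 7.32 and 10.75 to 10.92. The count of 0 genes at an adjusted p under 0.05 depended on single arrays. It was 26 without control replicate 3, 11 without control replicate 4, 5 without 8 h replicate 4, 1 without 1 h replicate 2 and 0 without any other array. In data simulated with these spreads, the test recovered 84.4% of 200 genes changed by a factor of 2 and 52.5% of those changed by a factor of 1.5 in this comparison, with noise drawn independently for each gene. All 200 changed in the same simulated data. With fewer changed genes the adjustment over all genes is stricter, and the share recovered then was not determined.

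Between 8 h and 1 h, ribosomal protein genes were higher at 8 h by a mean of 0.05, with 18 of 22 members higher (camera adjusted p = 0.0447, and adjusted p = 0.785 with an estimated correlation). RPL19 had a difference of 0.14 (SE 0.06), RPL32 0.11 (SE 0.07) and RPS16 0.11 (SE 0.06), and 0 members passed adjusted over the list alone or over all genes by limma, with 1 higher at an unadjusted p under 0.05. The mean was 0.00 with quantile normalization (camera adjusted p = 0.965) and -0.03 without probe sets that can match several transcripts (camera adjusted p = 0.979), where RPS16 had -0.04. The call also ended with median centring (0.03), and with no filter, a filter at the 75th percentile or the 8 arrays of these groups alone (each 0.05). It ended without control replicate 1 or 2 (each 0.05), 1 h replicate 2 (0.05), 1 h replicate 3 (0.04), 1 h replicate 4 (0.04), 8 h replicate 1 (0.02) or 8 h replicate 2 (0.05). The matrix list had a mean of 0.09, with 19 of 23 members higher at 8 h than at 1 h, and the hypoxia list -0.06, with camera adjusted p of 0.0634 and 0.278. Limma called 0 of 11805 genes, with 288 higher and 273 lower at an unadjusted p under 0.05. Their sum of 561 lay below the 590 given by chance on the assumption used at 1 h. Other groupings of the same 8 arrays gave 264 to 848. Between 8 h and 1 h 3.72% of genes had groups that did not overlap, against 2.86% by chance. The variances in limma's test also drew on the control arrays, so a sum below 590 does not show that these groups were alike. HTATSF1, a transcription elongation and splicing factor, had -0.41 (SE 0.07, adjusted p = 0.167), CTSZ, a lysosomal cathepsin, 0.68 (SE 0.13, adjusted p = 0.304), and CST3, the protease inhibitor cystatin C, 0.55 (SE 0.11, adjusted p = 0.304), the last with 1 of its 3 probe sets higher.

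The differences at 1 h and at 8 h were measured against the same 4 control arrays and correlated across 11805 genes at r = 0.704, with a covariance of 0.0374. Simulated unchanged groups against shared controls gave a mean r of 0.50 and a covariance of 0.0173, with the spread of the 3 groups taken as equal, and the covariances differed by 0.0201. This difference was 0.0086 without control replicate 1, 0.0101 without replicate 2, 0.0336 without replicate 3 and 0.0374 without replicate 4. It was 0.0186 to 0.0215 when a single exposed array was left out. With control replicates 1 and 2 left out, r was 0.655 and the covariance 0.0300, against 0.665 and 0.0295 in simulated unchanged groups with as many arrays. When the controls were split so that each time had its own pair, r was 0.317, 0.322, 0.323 and 0.318 in the splits that parted control replicates 1 and 2. It was 0.06 and 0.03 in the splits that kept them together. Genes are not independent replicates, and no test of r was made.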

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

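The tests of signal scaling, host brain tissue, myeloid and red blood cells, left-out pairs of controls, vascular and stromal cells, and the splits of the matrix list were chosen after the results they bear on had been seen. Of 309 groups of 4 arrays examined, 9 held an array far from its group by Dixon's ratio at its 95% critical value, and chance gives about 1 in 20, or 15.5.

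In the list of RGD-containing ligands and matrix proteins, replicate 3 at 1 h lay far from its group, at 0.0057 relative to the mean of all arrays against -0.17 to -0.15 on the other 3. FN1, the fibronectin gene, had a log2 signal of 11.01 in 1 h replicate 4 and 11.40 to 11.44 in the others of its group. DDIT4, an inhibitor of mTOR signalling, had 11.53 in 1 h replicate 3 and 11.78 to 11.83 in the others. HMGCS1 of cholesterol synthesis had 7.43 in 8 h replicate 1 against 8.11 to 8.21. COX4I1 of cytochrome c oxidase had 11.69 in 1 h replicate 4 against 11.59 to 11.60. For the ribosomal protein genes, RPL19 had 12.75 in control replicate 1 against 12.84 to 12.85, and RPL32 had 13.40 in 1 h replicate 1 against 13.21 to 13.22. GAD1, an enzyme of GABA synthesis, had 8.68 in control replicate 3 against 8.44 to 8.47. ITGA5, the α subunit of the fibronectin receptor, had 8.31 in 8 h replicate 4 against 8.88 to 8.98. The ribosomal protein list differed between the exposure times by 0.053 (camera adjusted p = 0.0447, and adjusted p = 0.785 with an estimated correlation).

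Control replicates 1 and 2 stood apart from the other 10 arrays, with higher matrix, cholesterol, hypoxia and immediate early genes and lower interferon and DNA replication genes. The immediate early list means were 0.33 and 0.33 in this pair, against -0.14 to 0.02 on the other 10 arrays. The tables argue against the signal distribution or its scaling as the whole source, since 101% of the gap on the first principal component was left after quantile normalization. More myeloid and red blood cells remain a candidate explanation: 3 of 5 tested markers (AIF1, FCER1G and HBB) were higher in both arrays than in each of the other 10, while LAPTM5 and CSF1R were not, and a mouse source could reach these human probe sets only by cross-hybridisation. The share of all genes that were higher in this way was not determined, and HBB was the only red-cell marker tested. More host brain tissue cannot be told apart from other sources. The neuron means of the pair were 0.05 and 0.13 against up to 0.19 elsewhere, and the oligodendrocyte means were 0.25 and 0.15 against up to 0.23. The astrocyte means were -0.08 and -0.11 against -0.17 to 0.13, so neither array was the highest for neuron or astrocyte markers. Other biological or technical differences among the control samples stayed untested, since no label divides them.

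Most list calls against the control may rest on control replicates 1 and 2. Without this pair 2 lists were called at 1 h and 8 h together, against 10 to 21 without any other pair of controls. Of the 8 lists called at 1 h and the 5 at 8 h with all controls, 1 was called in both fits, the matrix list at 1 h, and the other call without the pair, angiogenic factors at 1 h, was newly gained. Neither of these 2 calls without the pair held by camera with an estimated correlation (adjusted p = 0.954 for each). The highest count, 21, followed when replicates 3 and 4 were left out, and limma then called 1360 genes at 1 h and 1725 at 8 h, against 0 for each of the other 5 pairs. The exposure and the tumour coincide with the group in every case, so an effect of cilengitide stays open and cannot be told apart from a difference between tumours.

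The matrix list was lower at 1 h both with all controls (-0.27) and without control replicates 1 and 2 (-0.15, camera adjusted p = 0.00497), but its call was lost in both fits with an estimated correlation (adjusted p = 0.785 and 0.954) and by fry (adjusted p = 0.324 and 0.777), and the microglia and macrophage list moved with it (-0.20 to -0.02 on the 1 h arrays, and 0.13 and 0.02 in control replicates 3 and 4). For a list picked from 26 pathway lists after it was seen to be lower, the 35 splits of the 8 arrays are too few to decide on another choice of arrays: the real difference was 0.27, the highest other 0.26, and only the real split was as large. Other integrin subunits, a list that camera did not call, reached the same smallest exact permutation p of 0.0286 at 1 h. Fewer host vascular and stromal cells at 1 h might contribute and cannot be told apart, since the pericyte list differed by -0.085 from control replicates 3 and 4 with an SD of 0.19 among the 1 h arrays. An early response of matrix genes to integrin blockade and a difference between the control tumour and the 1 h tumour are both open and untested.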

How the results depend on the processing

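The fits without control replicates 1 and 2 were chosen after the data had been seen; the others were planned. The counts of 0 genes at 1 h and 8 h and between the times (limma; 1124, 1744 and 561 genes at an unadjusted p under 0.05) stayed at 0, and the counts of list calls, 14 in all (8, 5 and 1), stayed within 1.5 times, except as follows, and the cause was not tested unless given. Without probe sets that can match several transcripts, 1 gene was called at 1 h, and list calls were 7 in all (5, 2 and 0), and the ribosomal list between the times turned to -0.034. With all probe sets, 1 was called between the times. List calls between the times were 2 with a pseudocount of 64 and 0 with quantile normalization, median centring, no filter, a filter at the 75th percentile or only the 2 groups compared. Calls against the control were lost too: quantile normalization left 11 in all (7, 4 and 0) and the filter at the 75th percentile 12 (7, 5 and 0), and with no filter the protease list at 1 h and the matrix list at 8 h lost theirs. Each of these settings also newly called at least 1 other list against the control, so that no filter gave 14 in all (8, 6 and 0). An estimated inter-gene correlation and fry left 0 list calls in all and in each comparison, and both by construction allow for genes moving together.

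Without control replicates 1 and 2, which leaves fewer arrays, list calls were 2 in all (2, 0 and 0) and the correlation of effects was 0.655 (0.665 in simulated unchanged groups with as many arrays), and 3 means of called lists turned sign: oxidative phosphorylation to -0.020 at 1 h and -0.00023 at 8 h, and interferon response to -0.0066 at 8 h. Angiogenic factors were newly called at 1 h (0.22, camera adjusted p = 0.0330, and adjusted p = 0.954 with an estimated correlation). The correlation was 0.629 with no filter. With the controls split it was 0.0561, 0.317, 0.322, 0.323, 0.318 and 0.0308. Leaving out each array in turn gave 0 to 1 genes at 1 h, 0 to 26 at 8 h and 0 between the times, 7 to 19 list calls in all, 5 to 10 at 1 h, 2 to 8 at 8 h and 0 to 3 between the times, and correlations of 0.650 to 0.791 (0.461 to 0.571 simulated). The highest counts, 26 genes and 19 lists, came without control replicate 3, and the lowest list count, 7, without control replicate 1.

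Replicate numbers were not taken to pair the samples, since no label says so and only 1 of 12 same-number pairs of arrays, 4 for each comparison, had a correlation of deviations over 0.1 (-0.08 to 0.10). In 8 of the 12 the array correlated best with its own number, against about 3 by chance, a hint from the data and not from the design. With the number as a replicate block, limma called 0 genes in each comparison and camera 18 lists in all (9, 6 and 3), adding other integrin subunits at 1 h, immediate early genes at 8 h, and matrix and glycolysis genes between the times (adjusted p = 0.0492 for each). The block was fitted only with the preset inter-gene correlation. Without a block, no list was called with an estimated correlation. Among other results, 2868 values of named genes stayed on their side, 41 values that had not passed changed sign and 14 newly passed, and of the called lists 276 values stayed, 83 lost the call and 4 turned sign. Only genes with a mean signal of at least 31.9 were tested, so dimmer genes have no result outside the fit with no filter.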

Other observations

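A few members each of several lists, most of them not called as lists, passed at 1 h or 8 h when adjusted over their own list alone, though 0 passed over all genes by limma, with 1124 and 1744 at an unadjusted p under 0.05. No correction was made over the lists and times. Adjusted over all genes, limma's p for the members of any list that passed in this way was 0.112 to 0.458. ETV5, a transcription factor induced by MAPK signalling, was the 1 of 15 members of the MAPK feedback list that passed at each time, with log2 differences of 0.37 at 1 h and 0.39 at 8 h (SE 0.10). The early response genes DUSP1, a phosphatase that turns off MAP kinases, and EGR3 had -0.34 (SE 0.10) and -0.65 (SE 0.20) at 8 h. Among p53 targets, the death receptor TNFRSF10B had -0.23 at 1 h and -0.27 at 8 h (SE 0.07), MDM2, which degrades p53, had -0.39 at 8 h (SE 0.12), and the secreted factor GDF15 had 0.57 and 0.53 (SE 0.17). SMURF2, a ubiquitin ligase of the TGF-β pathway, had -0.48 (SE 0.12) at 8 h, and the chemokine CCL2 had 0.25 (SE 0.06). In focal adhesions PTK2, the focal adhesion kinase, had 0.31 (SE 0.09) and its substrate BCAR1 -0.72 (SE 0.22) at 8 h. The protease ADAM10 had -0.35 (SE 0.09), the chaperone HSPB1 0.30 (SE 0.08), the helicase subunit MCM2 0.43 (SE 0.12) and NES, the stem cell filament nestin, 0.31 (SE 0.07) at 8 h. RPL8, RPL3 and RPL19 had 0.24, 0.24 and 0.19, GAD1 had 0.38 (SE 0.09), and THBS1 of the angiogenic list had -0.42 (SE 0.10). At 1 h KIF20A, a mitotic kinesin, had 0.35 (SE 0.09), S100A11 of the mesenchymal list -0.69 (SE 0.20) and CLDN11, a claudin of myelin, -0.70 (SE 0.23). Without control replicates 1 and 2, a setting chosen after the data had been seen, many of these values were smaller. At 1 h GDF15 then had 0.25, KIF20A 0.21, S100A11 -0.17, ETV5 0.26, TNFRSF10B -0.23 and CLDN11 -0.67. At 8 h MCM2 had 0.16, GDF15 0.21, SMURF2 -0.24, EGR3 -0.34, DUSP1 -0.23, RPL3 0.12, RPL8 0.18, RPL19 0.16, ADAM10 -0.19, PTK2 0.17, HSPB1 0.17 and NES 0.21. Also at 8 h BCAR1 had -0.62, ETV5 0.28, TNFRSF10B -0.27, MDM2 -0.29, CCL2 0.17, THBS1 -0.32 and GAD1 0.32.

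The remaining pathway lists were not called in the fit over all 12 arrays without a block. Mean differences at 1 h, at 8 h and between the times were -0.19, -0.09 and 0.10 for other integrin subunits, -0.06, -0.02 and 0.04 for focal adhesion, -0.14, -0.13 and 0.01 for YAP/TEAD targets, and 0.01, 0.06 and 0.05 for SRF and actin targets. Immediate early genes had -0.17, -0.19 and -0.02, with camera adjusted p of 0.0752 at 1 h and 0.0634 at 8 h (0.0317 at 8 h with quantile normalization, and adjusted p = 0.785 with an estimated correlation) and 12 of 16 members lower at each. MAPK feedback genes had -0.02, -0.07 and -0.06, NF-κB inflammatory genes -0.02, -0.08 and -0.05, and TGF-β targets -0.11, -0.07 and 0.04. Mitosis genes had 0.07, 0.07 and 0.00, p53 targets -0.06, -0.07 and -0.00, apoptosis regulators -0.01, 0.01 and 0.01, and genes of the unfolded protein and integrated stress response -0.04, -0.02 and 0.03. Angiogenic factors had 0.04, -0.07 and -0.11, mesenchymal glioblastoma genes -0.03, 0.04 and 0.07, proneural and stem genes 0.06, 0.07 and 0.01, and glycolysis genes -0.06, 0.01 and 0.07. Lists called in 1 comparison had other means elsewhere: at 8 h DNA replication had 0.10 (camera adjusted p = 0.0724), heat shock 0.10 and matrix proteases -0.12, and ribosomal proteins had 0.01 at 1 h and 0.06 at 8 h. Many of these means turned sign without control replicates 1 and 2. At 1 h immediate early genes then had 0.04, MAPK feedback 0.04, NF-κB 0.10, mitosis -0.03, SRF and actin targets -0.03, apoptosis regulators 0.01, mesenchymal genes 0.02 and proneural genes -0.03. At 8 h immediate early genes had 0.02, NF-κB 0.05, mitosis -0.03, DNA replication -0.05, heat shock -0.05, angiogenic factors 0.11, proneural genes -0.02, focal adhesion 0.01 and the stress response 0.00. Others came closer to 0 without turning, such as YAP/TEAD targets at -0.02 and -0.01, p53 targets at -0.02 and -0.02 and matrix proteases at -0.02 at 8 h, while angiogenic factors at 1 h had 0.22. The mean, the median and the test differed in sign for 5 lists at 1 h (focal adhesion, SRF and actin targets, apoptosis regulators, ribosomal proteins and neuron), 4 at 8 h (focal adhesion, apoptosis regulators, stress response and astrocyte) and 1 between the times (mitosis), all of them lists that were not called.

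Markers of brain cell types were not called either. Mean differences at 1 h, at 8 h and between the times were -0.07, -0.11 and -0.04 for neuron, -0.22, -0.03 and 0.19 for oligodendrocyte, -0.03, 0.03 and 0.06 for astrocyte and -0.15, -0.21 and -0.06 for pericyte, whose 5 tested members all had lower means at both times. Described without a camera test, 3 endothelial markers had -0.22, -0.07 and 0.15, 4 microglia and macrophage markers -0.41, -0.48 and -0.08, and HBB of the red blood cell list -0.59, -0.48 and 0.10. Against control replicates 3 and 4 alone, the 1 h and 8 h differences were -0.18 and -0.26 for microglia and macrophages, -0.14 and -0.04 for HBB, -0.14 and 0.01 for endothelium, -0.10 and 0.09 for oligodendrocyte, -0.13 and -0.07 for astrocyte, -0.04 and -0.08 for neuron and -0.08 and -0.15 for pericyte. How many of these markers the tumour cells also express was not determined.

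Differences of at least a factor of 2 with groups that did not overlap were found for 5 genes at 1 h, 19 at 8 h and 4 between the times, and 0 reached a factor of 4. Each comparison was set beside the 35 splits of its 8 arrays into 4 and 4, and the counts of splits as large include the real one. For genes with an adjusted p under 0.05 the real count was 0 in each comparison, which all 35 splits must reach, so these splits say nothing about chance; the highest other split gave 1 at 1 h, 2 at 8 h and 1 between the times. For genes at an unadjusted p under 0.05, the real split at 8 h gave 1744 genes, the highest other 1642, and 1 of 35 was as large. This was 1 of 9 such counts, with no correction over them. The splits do not exclude chance even for this count alone, since most of their spread followed control replicates 1 and 2. Other splits that kept this pair together gave 1096 to 1642 genes, and splits that parted it 265 to 589. The real count at 8 h was 877 without control replicates 1 and 2 and 3486 without control replicates 3 and 4. Chance was not excluded either at 1 h (1124 genes, highest other 1615, 11 splits as large) or between the times (561 genes, highest other 848, 8 splits as large). The split with 1615 genes placed control replicates 1 and 2 with 1 h replicates 1 and 2. For called lists chance was not excluded: 8 at 1 h against a highest other of 10 (5 splits as large), 5 at 8 h against 10 (14 splits) and 1 between the times against 9 (28 splits). Correlations between arrays did not set the groups apart, with a mean r of 0.980 within groups (SD 0.00196, 13 pairs) and 0.980 between groups (32 pairs) over the 10 arrays other than control replicates 1 and 2.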
